A study of Arabidopsis thaliana with 2 samples.

How the data were processed

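Leaves of soil-grown Arabidopsis thaliana were profiled by sequencing of cDNA from transcript 3' ends on an Illumina Genome Analyzer II. Per the labels' protocols, plants were kept in a greenhouse with light for 12 h a day, 24 °C by day and 20 °C at night, 60% humidity, a light level between 70 and 80 µmol per square metre and second and 370 µmol of CO2 per mol of air, and RNA came from 10 plants of each genotype at 3 weeks of age. The labels' protocols say that a company built the libraries and controlled read quality. The genome build was TAIR9, per the submitters' processing notes. The aligner, the counting tool, the use of strand and the treatment of reads that match several loci are not given in the sources used here.

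The deposited values are whole-number read counts per locus, per the file headers 1 column per genotype, with no normalization by the authors that the values show. Each file listed 27337 rows, of which 1 locus (AT4G32850) appeared more than once with the same value and was kept once, leaving 27336 loci. Both copies of 2 genes in the chloroplast inverted repeat held identical counts in each library (ATCG00830 and ATCG01310 3369 in the wild type and 2437 in the mutant, ATCG00900 and ATCG01240 4250 and 4033). A read matching both copies was therefore counted at each, or shared equally between them, in these cases. Genes with near-identical copies (such as the PDF1.2, RBCS and LHCB1 genes) or overlapping neighbours are uncertain. No sample or column was left out. Symbols and product names came from the RefSeq table of assembly TAIR10.1, where 26604 loci matched and 732 did not. Transcript lengths, GC content and the PIP transcript sequences came from the same assembly, which differs from the build of the counts. No coordinates are printed for that reason. The unmatched loci, which include the organelle-encoded ones, held 2.29% of reads in the wild type and 2.23% in the mutant and stayed in all tests.

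Library sizes were scaled by TMM factors (0.976 and 1.02) from edgeR 4.0.16 in R 4.3.3, and CPM values refer to these effective sizes. With 1 library per genotype there are no residual degrees of freedom, so the edgeR quasi-likelihood test could not be fitted and no test of the genotype was made. Instead the reads of each gene were compared by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 15111 genes with at least 20 reads over both libraries. A gene was called when the adjusted p was under 0.05, the 95% Clopper-Pearson interval of the log2 ratio excluded 0 and the ratio was at least 2-fold. This test covers counting error only. Reads carry no molecular identifiers, so they are not independent molecules. A count of 0 allows up to 3 reads, or 0.754 CPM in the wild type and 0.724 CPM in the mutant. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

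In total 29 gene lists covering 551 loci were fixed before the data were examined, with 550 of these loci in the files, and 3 lists were defined by rule (chloroplast-encoded, mitochondria-encoded and cytosolic ribosomal proteins by product name). No listed locus carried a conflicting symbol in the reference table. For each list the members called were counted, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list stood apart outside the middle 95% of these random lists. These percentiles describe the 2 libraries and are not tests of the genotype. The rule for the genes to be named was also fixed beforehand. It took PIP1;2 with 5 loci on each side, the 15 called genes in each direction whose interval bound nearest to 0 was farthest out, and in each list up to 4 called members, or up to 2 abundant members besides where fewer than 2 were called. The aquaporins PIP1;1, PIP1;3, PIP1;4, PIP1;5, PIP2;1, PIP2;8, NIP1;2 and NIP6;1, and the list members PRR5, HSP70-4, DIN10, ERF6 and ERF105, are named outside this rule and were chosen after their values had been seen. The aquaporin median was taken without PIP1;2. The floral list had 1 tested member and got no percentile.

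The calling rule was tested on simulated data with 200 seeded changes among the real genes. With counting error alone it called 98% of 50 genes raised 4-fold, 92% of 50 raised 3-fold, 89.1% of 46 lowered to 0.25 of their level and 3 of 14905 unchanged genes, and 0 of 50 raised 1.5-fold. Alternatives changed the library sizes (total counts, DESeq2 1.42.0 median-of-ratios factors, 11 reference genes, or totals without organelle genes and the 20 most abundant genes), thinned the deeper library, changed the read minimum or the fold, and replaced the test by the edgeR exact test with assumed biological coefficients of variation. A correction for transcript length and GC content, and families of genes sharing a product name apart from its numbers, were added after the data had been seen.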

Results

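Gene expression was measured in leaves of Arabidopsis thaliana (thale cress) of the Columbia ecotype, in a wild-type line and in the mutant line atpip1;2-1, which is deficient in the plasma membrane aquaporin PIP1;2. Aquaporins are membrane channels for water, and PIP1;2 has also been studied as a path for carbon dioxide into leaf cells. Each genotype was represented by 1 library made from the pooled leaves of 10 plants that were 3 weeks old. The wild-type library held 4079098 reads over 27336 loci and the mutant library held 4041759. A read was counted at 19363 loci in the wild type and at 19441 in the mutant. With 1 library per genotype there was no replicate check. The intervals of levels and of log2 ratios, given at the 95% level, cover counting error only. Bootstrap intervals of differences between list medians, given near the end, do not measure spread between pools either. A gene is called higher or lower below when the reads of these 2 libraries differed by the exact test and by at least 2-fold. This compares the libraries and not the genotypes. A gene that is not called can still differ in its reads by less than 2-fold. The comparison addressed which leaf transcripts differ in a plant that lacks normal levels of this aquaporin.

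The mutated gene itself was the first check of the labels. PIP1;2 (AT2G45960, chromosome 2) fell from 4211 reads in the wild type to 566 in the mutant library. This was 1058 CPM (read count scaled to the effective library size, 95% interval 1026 to 1090) against 137 CPM (126 to 148), a log2 ratio of -2.95 (-3.08 to -2.83). The mutant library thus retained 12.9% of the wild-type level (11.8% to 14.1%). PIP1;2 was among the most abundant aquaporin transcripts of the wild-type library, next to the vacuolar aquaporins TIP1;2 at 1215 CPM and TIP2;1 at 1137 CPM. None of the 20 other aquaporin genes with enough reads was called, and their log2 ratios ran from -0.73 for PIP2;8 to 1.14 for NIP1;2. NIP6;1, with 53 and 107 reads (0.96, 0.47 to 1.46), passed the rule at 1.03 with total counts as library sizes or totals without organelle and abundant genes, and at 1.06 after correction for transcript length and GC content. Among the closest relatives, PIP1;1 had a log2 ratio of 0.29, PIP1;3 of 0.00, PIP1;4 of -0.25 and PIP1;5 of 0.40, while PIP2;1 had 0.37. Apart from TIP1;2 and TIP2;1, the other aquaporins named here were chosen after their values had been seen. TIP1;2 was at 1196 CPM in the mutant (log2 ratio -0.02) and TIP2;1 at 960 CPM (-0.24). The median of the aquaporins without PIP1;2 was 0.10, at the 97.2 percentile of random gene lists of like expression and just inside the middle 95% of them. Of the 10 genes next to PIP1;2 in locus order, 7 had enough reads and 0 were called by the exact test of the reads, with log2 ratios between -0.19 and 0.16. Reads came from the 3' ends of transcripts and the site of the mutation is not given in the sources used here, so they do not show whether the remaining transcript was intact.

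**Figure D1:**
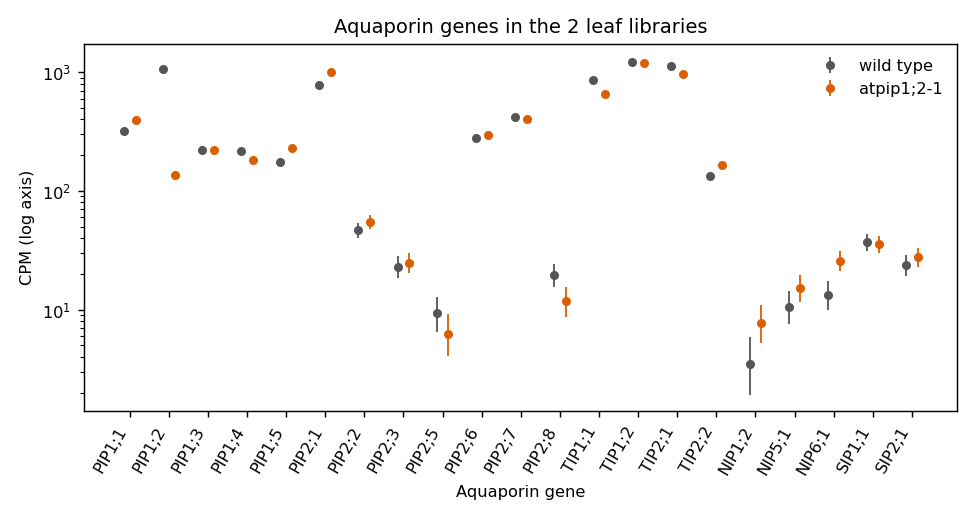
Aquaporin genes with at least 20 reads over both libraries, in CPM on a log axis. Points are the single wild-type and mutant libraries and bars are 95% counting intervals. PIP1;2 lies at 1058 CPM in the wild type and 137 CPM in the mutant, and no other member was called with the main scaling.

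Of 15111 genes with at least 20 reads over both libraries, 197 were higher and 166 were lower in the mutant library by at least 2-fold. Plant defensins, small antimicrobial peptides, made up 4 of the 15 higher genes named here, which were ranked by the interval bound nearest to 0 and not by fold, so that they leave out some of the 27 genes higher by at least 4-fold. PDF1.2c (AT5G44430) went from 5 to 219 reads (log2 ratio 5.40, 4.15 to 7.03). PDF1.2A (AT5G44420) went from 15 to 403 reads (4.69, 3.95 to 5.54), PDF1.2B from 4 to 48 (3.53) and PDF1.3 from 6 to 44 (2.82). These genes are near-identical copies, so the split of reads among them is uncertain. Other defence-related genes were PR4, a chitin-binding pathogenesis-related protein, at 12.6 CPM in the wild type and 68.8 CPM in the mutant (2.45, 2.02 to 2.92), and AT4G16260, a glycosyl hydrolase, with 1 and 53 reads (5.67, 3.13 to 11.00). CML41, a calmodulin-like calcium sensor, rose from 7 to 90 reads (3.63), and CAX3, a vacuolar cation exchanger, from 86 to 374 (2.06). GASA1, a gibberellin-regulated peptide, was the most abundant of the 15, with 52.0 CPM against 253 CPM (2.28, 2.07 to 2.51). The senescence-related transcription factor NAP rose 5.47-fold (16 to 91 reads), and the dynamin gene DL3 rose 4.42-fold. NATA1, an N-acetyltransferase, rose 6.73-fold, the glycine-rich protein AT2G05540 7.54-fold and the acyltransferase AACT1 (AT5G61160) went from 1 to 27 reads. AT3G15450, an aluminium-induced protein, rose 3.42-fold.

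The 15 lower genes named here were ranked in the same way and leave out some of the 15 genes lower by at least 4-fold. MAF5 (AT5G65080), a MADS-box transcription factor of the flowering-repressor clade, fell from 107 reads to 4 (log2 ratio -4.80, -6.70 to -3.40) and had the largest decrease of the 15 named genes. AT3G59890, annotated as a dihydrodipicolinate reductase, had 25 reads in the wild type and 1 in the mutant (-4.70, -10.06 to -2.09). The RNA methyltransferase gene AT3G21300 went from 49 reads to 9 (-2.50), the pentatricopeptide repeat gene AT4G13650 from 19 to 2 (-3.30, -6.45 to -1.25) and the oxygenase gene AT5G51310 from 20 to 3 (-2.79, -5.19 to -1.04). Genes for plastid proteins were among the 15. CPN60A, the alpha subunit of the plastid chaperonin that folds proteins such as Rubisco, fell from 288 CPM to 101 CPM (-1.52, -1.68 to -1.36), and Cpn60beta2 from 127 CPM to 52.6 CPM (-1.27). FLN2, a fructokinase-like plastid protein, fell from 65 reads to 18 (-1.91). FIB2, a fibrillarin of the nucleolus, fell from 102 reads to 34 (-1.64). GER3, a germin, fell from 214 CPM to 80.2 CPM (-1.42), the copper amine oxidase gene AT1G31690 fell by 1.78 on the log2 scale, PDE340 by 1.54 and AT5G48470 by 1.61. The iron-response regulator BHLH38 also ranked here (-1.89). PIP1;2 was the remaining member of the 15.

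**Figure D2:**
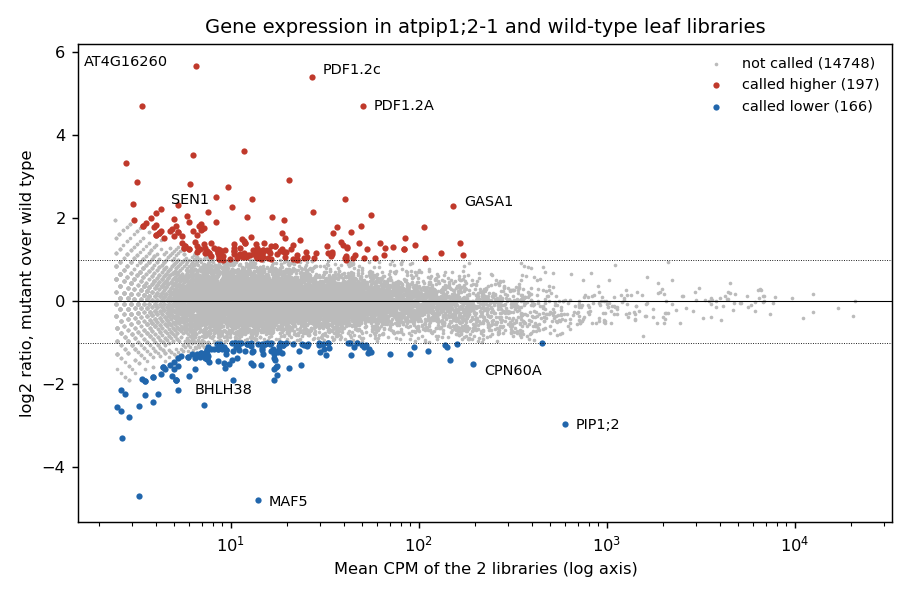
The log2 ratio of the mutant over the wild-type library against mean CPM (log axis) for 15111 genes, 1 point per gene. Dotted lines mark a 2-fold difference, red points are the 197 genes called higher and blue points the 166 called lower. PIP1;2 stands apart among the abundant genes at a log2 ratio of -2.95.

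The split between higher and lower genes depended on scaling. With total counts as library sizes 252 genes were higher and 118 lower, without organelle genes and the 20 most abundant genes 254 and 118, and with 11 reference genes 166 and 216. Plant-to-plant spread was not measured, and for the 1067 genes with at least 1000 reads the log2 ratios had a robust SD of 0.36 against 0.07 from counting alone. In a simulation of unchanged genes with an assumed biological coefficient of variation of 0.2, the same rule called 590 of 14831 genes, more than the 363 called here, and with 0.1 it called 45 of 14862.

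Genes that are normally repressed by sugar and induced by carbon starvation were higher together in the mutant library. Of 21 tested members, 8 were called higher (1 of them, DIN10, lost at 0.98 with reference genes as the scale) and 0 lower, 20 had a positive log2 ratio, and the median was 0.87, above all 10000 random lists of like expression (percentile 100). SEN1 (AT4G35770), also known as DIN1, went from 14 to 70 reads (2.26, 1.42 to 3.21). KMD1, a kelch-repeat F-box protein, went from 22.1 CPM to 56.7 CPM (1.36), DRM2 (AT2G33830), a dormancy-associated gene, from 49.0 CPM to 117 CPM (1.26), and BT2, a scaffold protein of sugar and nitrogen responses, from 24.4 CPM to 58.9 CPM (1.27). The leaf senescence list was also higher, with a median of 0.57 (percentile 99.98), 1 member called (NAP) and all 8 tested members positive. SAG21 was at 42.2 CPM in the wild type and 81.1 CPM in the mutant (0.94), and was called at 1.01 with total counts as library sizes or totals without organelle and abundant genes. NYC1, an enzyme of chlorophyll b breakdown, was at 49.2 and 68.8 CPM (0.48).

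Genes of photosynthetic carbon metabolism did not pass the 2-fold rule. In photorespiration, the salvage of the oxygenation product of Rubisco, 0 of 29 tested genes were called by the exact test with the 2-fold rule, but 27 had a negative log2 ratio and the median was -0.27 (percentile 5.48 among lists of like expression). SHM1, the mitochondrial serine hydroxymethyltransferase, was at 2251 CPM against 1858 CPM (-0.28), and GLN2, the plastid glutamine synthetase, at 1868 against 1652 CPM (-0.18). In the Calvin-Benson cycle 0 of 23 genes were called, 19 were negative and the median was -0.30 (percentile 5.68). RBCS1A, a small subunit of Rubisco, had 23128 CPM in the wild type and 17918 CPM in the mutant (-0.37), and RBCS3B had 17833 and 15946 CPM (-0.16). Both lists fell beyond the lower bound only when random lists were not matched on expression (percentiles 0.23 and 0.22). The light-harvesting complex genes had a median of 0.09, with 0 of 20 called. They stood above lists of like expression (percentile 99.58) but not above unmatched lists (78.34). LHCB1.3 was at 21077 and 20970 CPM (-0.01) and LHCB1.5 at 11706 and 13204 CPM (0.17). Nuclear photosystem and electron transport genes had a median of -0.01 (percentile 96.24) with 0 of 30 called, with PSBR at 9432 and 9920 CPM (0.07) and PSAO at 6813 and 6848 CPM (0.01). The 55 tested chloroplast-encoded genes had a median of -0.06 (percentile 38.41) with 0 called, among them ATCG00470 at 4677 and 3439 CPM (-0.44) and ATCG00440 at 3602 and 3679 CPM (0.03).

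Among the carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, 1 of 7 tested genes was called. BCA6 went from 26.9 CPM to 55.1 CPM (log2 ratio 1.03, 0.70 to 1.38), a call lost at 0.98 when reference genes set the scale and at 0.97 after correction for transcript length and GC content. The abundant BCA1 was at 3708 and 2800 CPM (-0.41) and BCA2 at 2330 and 1918 CPM (-0.28), and the list median was 0.01 (percentile 68.47). Starch and sucrose metabolism had 0 of 25 genes called and a median of -0.07 (percentile 31.54), with the triose phosphate transporter TPT at 1133 and 1047 CPM (-0.11) and the amylase BAM3 (AT4G17090) at 347 and 304 CPM (-0.19). In nitrogen assimilation 1 of 17 genes was called, NIA1, a nitrate reductase, from 42.5 CPM to 104 CPM (1.29, 1.03 to 1.56). The second nitrate reductase gene NIA2 was at 453 and 577 CPM (0.35) and GLN1;2 at 445 and 378 CPM (-0.23), and the list did not stand apart (median 0.07, percentile 88.66).

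Stress and defence lists were mostly shifted upward. Of 26 tested genes of the rapid wound and touch response, 6 were called higher and 0 lower, 25 were positive and the median was 0.70 (percentile 100). The transcription factors WRKY33 (18.6 to 46.4 CPM, log2 ratio 1.32), ERF1A (26 to 79 reads, 1.55), ZAT10 (41.2 to 89.3 CPM, 1.12) and ERF2 (20.3 to 45.6 CPM, 1.17) were among them. The jasmonate list had 3 of 25 genes called, all higher, 21 positive and a median of 0.30 (percentile 100). The called members were PDF1.2A, PDF1.2B and ORA59, an activator of the defensins that integrates jasmonate and ethylene signals, which went from 9 to 39 reads (2.06, 0.99 to 3.29). PDF1.2A and PDF1.2B are near-identical copies with an uncertain split of reads, so they may not be separate calls. In the ABA, dehydration and cold list 3 of 22 were called higher, with a median of 0.41 (percentile 100). These were GOLS2 (12 to 45 reads, 1.85) and GOLS1 (35 to 79 reads, 1.12), which make galactinol, and the NAC factor RD26 (36 to 85 reads, 1.18). The salicylic acid list did not stand apart (median 0.14, percentile 92.6), with 1 of 16 called. EDS5, a transporter of the salicylic acid pathway, went from 25 to 71 reads (1.45, 0.77 to 2.17), whereas PR5 was at 209 and 228 CPM (0.12) and ACD6 at 334 and 372 CPM (0.16). In the heat shock list 0 of 9 were called. Its median of 0.31 lay at the 97.92 percentile but at 79.61 among genes with at least 100 reads. HSP70-4 (1.24) was called with total counts as library sizes or totals without organelle and abundant genes (both 1.31). The abundant chaperones HSC70-1 (956 and 893 CPM, -0.10) and HSP90-2 (238 and 159 CPM, -0.58) lay below 0.

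The cytosolic ribosomal protein genes were lower together in the mutant library. The list, defined by product name, covers only part of this class. Of its 13 tested genes 12 were negative, and the median of -0.69 lay below all random lists (percentile 0). A wider set of 291 tested nuclear genes with a product named ribosomal protein and no organelle in the name was compared after the data had been seen. In it 10 were called lower and 0 higher. This set can still hold organelle ribosomal proteins whose names do not say so. Among the 13, only AT3G44590, an acidic 60S protein gene, passed the 2-fold rule, from 41.7 CPM to 20.5 CPM (-1.02, -1.42 to -0.64). This call was lost with total counts as library sizes or totals without organelle and abundant genes (both -0.95). It was also lost after correction for transcript length and GC content (-0.80). The abundant AT1G01100 was at 712 and 414 CPM (-0.78) and AT2G27720 at 645 and 401 CPM (-0.69). Markers of dividing cells were negative in 9 of 9 tested genes with a median of -0.54 (percentile 0.27), though 0 were called. The DNA replication clamps PCNA2, with 50 and 38 reads, and PCNA1, with 43 and 36, had log2 ratios of -0.45 and -0.31. The translation elongation factor gene EF1A, a reference gene, was at 2006 CPM in the wild type and 1122 CPM in the mutant (-0.84). The 11 reference genes as a group had a median of 0.05 (percentile 81.95) with 0 called, and UBQ10 was at 1333 and 1549 CPM (0.22).

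The iron-status list holds ferritin genes besides genes of the iron deficiency response, so its median gives no direction of iron status. The list was shifted downward, with 3 of 12 called lower, 0 higher, and a median of -0.46 (percentile 0.05). The 3 were transcription factors that are induced by iron deficiency, namely BHLH38 (107 to 30 reads, -1.89, -2.53 to -1.30), BHLH100 (54 to 20 reads, -1.49) and BHLH39 (26 to 8 reads, -1.76). The flavonoid list had a median of -0.39 (percentile 0.6, and 3.69 by the mean) and members called in both directions. FLS1, flavonol synthase, fell from 78 reads to 28 (-1.53, -2.21 to -0.90), while MYBL2, a repressor of anthocyanin synthesis, rose from 38.4 CPM to 93.7 CPM (1.29). In cell wall expansion XTH24 rose from 20.8 CPM to 66.2 CPM (1.67, 1.31 to 2.04) and EXPA10, an expansin, fell from 25.4 CPM to 12.3 CPM (-1.04), a call lost with total counts as library sizes or totals without organelle and abundant genes (both -0.97) and after correction for transcript length and GC content (-0.95), with a median over 23 genes of -0.08 (percentile 30.03). Glucosinolate synthesis showed 0 of 24 calls and a median of -0.05 (percentile 57.13), with BCAT4 at 354 and 373 CPM (0.08) and CYP83A1 at 373 and 352 CPM (-0.08). Sulfur limitation had 1 of 6 genes called, LSU1 from 8 to 26 reads (1.64, 0.46 to 3.00), with APR2 at 146 and 130 CPM (-0.17), APR1 at 67.8 and 66.9 CPM (-0.02) and a median of -0.00 (percentile 52.15). Phosphate starvation had 0 of 5 called and a median of -0.10 (percentile 32.82), with SQD1 at 60.0 and 45.6 CPM (-0.40) and SQD2 at 25.9 and 24.1 CPM (-0.10).

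Clock genes served to compare the time of day of the libraries. Morning-phased genes had a median of 0.27 (percentile 99.3, and 97.09 by the mean) and evening-phased genes of 0.23 (percentile 95.66), with 0 of 13 and 0 of 11 called. LNK2 was at 119 and 124 CPM (0.06), COL2 at 107 and 116 CPM (0.12), GRP7 at 1772 and 2077 CPM (0.23) and GRP8 at 418 and 391 CPM (-0.10). PRR5 (0.94) was called with total counts as library sizes or totals without organelle and abundant genes (both 1.01), and after correction for transcript length and GC content (1.02). Among the markers of leaf cell types, epidermis markers had a median of 0.15 (percentile 89.54, 0 of 8 called), with LTP1 at 1144 and 823 CPM (-0.48) and CER6 at 233 and 329 CPM (0.50). Vascular markers had a median of 0.01 (percentile 62, 0 of 13 called), with TGG2 at 2894 and 1994 CPM (-0.54) and PP2-A1 at 230 and 237 CPM (0.04). Guard cell and stomatal lineage genes were negative in 9 of 10 with a median of -0.35 (percentile 2.06, and 5.52 by the mean). TGG1 was at 2352 and 1743 CPM (-0.43) and EPFL9, the stomagen peptide, at 35.7 and 20.8 CPM (-0.78), with 0 called. Of the floral markers 1 was tested, SEP1 (AT5G15800), with 22 and 11 reads (-1.06, -2.25 to 0.05). Mitochondria-encoded genes had a median of 0.18 (percentile 91.11) with 1 of 28 called higher (ATMG01080, 13 to 34 reads, 1.33) and 2 lower (ATMG00170 and ATMG00620, which both went from 32 to 9 reads, -1.89, identical counts that cannot be taken as separate calls). Adjusted over the list alone, the counts of called genes were those given except for 1 more higher gene each among the aquaporins, the heat shock genes and the senescence genes. In all, 8 of the 31 lists with a percentile stood apart as higher and 5 as lower. By chance 1.55 would be beyond the bounds if the members were independent random draws of genes. Genes of a list can move together, so this number is a loose guide only.

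**Figure D3:**
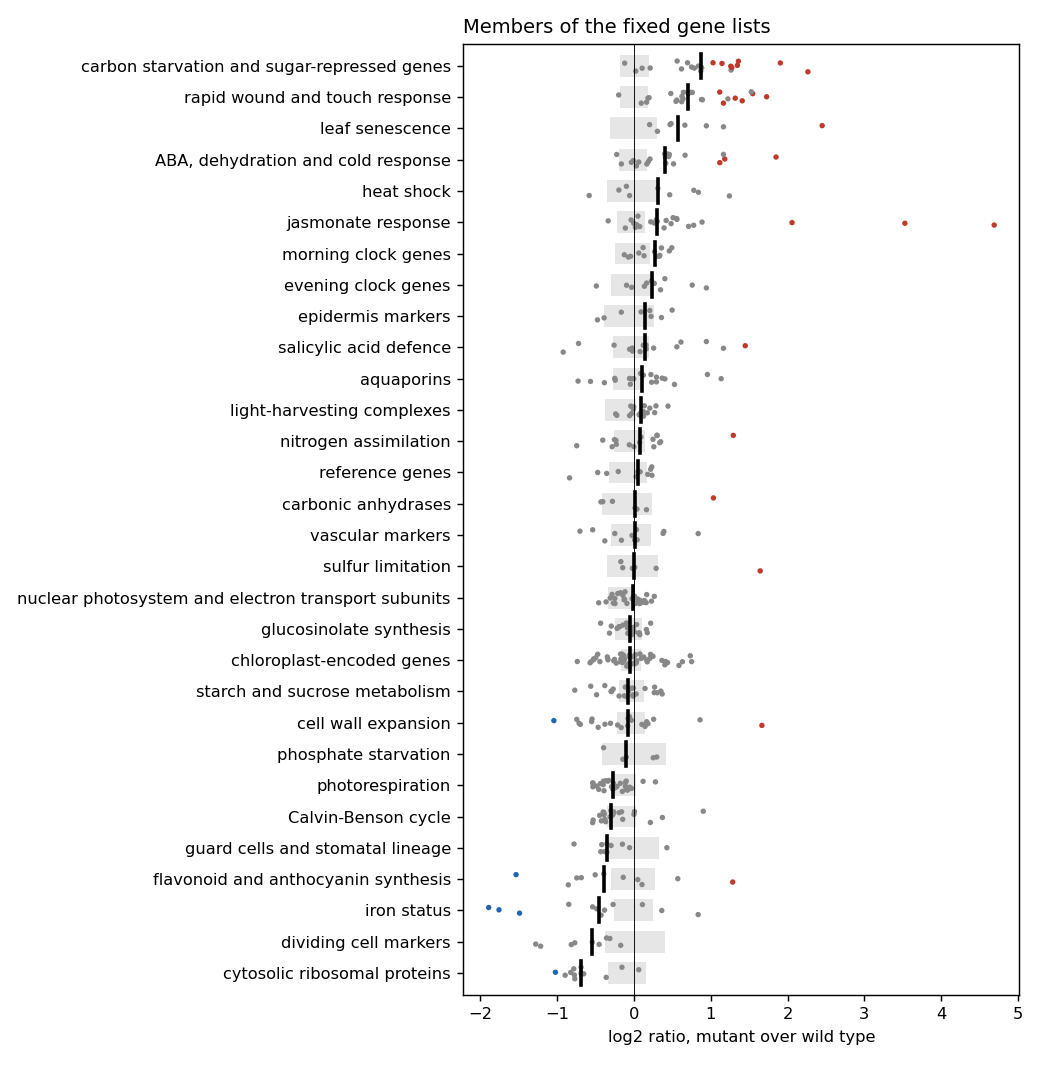
Members of the gene lists by log2 ratio of the mutant over the wild-type library, 1 point per tested gene, red when called higher and blue when called lower. Black bars are list medians and grey bands hold the middle 95% of the medians of 10000 random lists of like expression. The sugar-repressed list has the highest median, 0.87, and the cytosolic ribosomal protein list the lowest, -0.69.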

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

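No paired analysis was possible because each genotype had 1 library, and no replicate could be left out. The decrease of PIP1;2 was called under the 4 other scalings and after thinning, with a log2 ratio of -2.88 at its smallest, and was among the genes lost at an assumed coefficient of 0.4. The counts of genes moved by over 1.5 times with the read minimum, the fold and the assumed spread. With a minimum of 100 reads 97 genes were higher and 80 lower, at 1.5-fold 496 and 599, and at 4-fold 27 and 15. The edgeR exact test with an assumed biological coefficient of variation of 0.1 called 111 higher and 78 lower, with 0.2 it called 15 and 3, and with 0.4 it called 2 and 0 (13 lower at an unadjusted p under 0.05). The 3 lower genes at 0.2 were PIP1;2, MAF5 and AT3G59890, and the 2 higher genes at 0.4 were PDF1.2A and PDF1.2c. These tests assume a spread in place of measuring it. Of the 55 named called genes other than PIP1;2, 53 to 55 stayed called under the 4 scalings, 52 after correction for length and GC content (added after the data had been seen), 50 at an assumed 0.1, 16 at 0.2 and 2 at 0.4, and 0 reversed. The calls lost at an assumed 0.1 were those of LSU1, GOLS1, BHLH39, EXPA10 and ATMG01080, and among other list members those of ERF6 and ERF105. The named SAG21 and the list members NIP6;1, PRR5 and HSP70-4 were gained as calls with total counts and with totals without organelle and abundant genes. The scalings shifted the median of all tested genes by -0.05 to 0.07 on the log2 scale. Of 278 list percentiles under alternatives 262 kept their side of the bounds. The aquaporins crossed upward to 97.53 with total counts and without organelle and abundant genes, 97.57 with reference genes, 99.01 with no read minimum and 98.17 by the mean. Without matching on expression, photorespiration moved to 0.23, the Calvin-Benson cycle to 0.22, light harvesting to 78.34 and heat shock to 97.07. Heat shock was also at 93.98 with no minimum and 79.61 with a minimum of 100 reads. By the mean, salicylic acid defence was at 97.61, morning clock genes at 97.09, flavonoid synthesis at 3.69 and the guard cell list at 5.52, the last also at 5.9 with a minimum of 100 reads. The cause of these changes was not tested. Depth limits the low genes most, and the median called gene had 98 reads (higher) or 93.5 (lower) over both libraries.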

Other observations

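Families of genes whose annotated product names are the same once numbers are removed were compared after the data had been seen. Differently numbered families can thus be pooled, and 1 protein class can be split over several such names. Of 191 families with at least 10 tested members, 13 lay within the lowest 0.1% of random lists of like expression and 4 within the highest 0.1%. On each side 0.191 would be expected if the members were independent random draws of genes. Members of a family can move together, so this number is a loose guide only. Of the 13 low families 9 were ribosomal protein families. The others were histones (24 genes, median log2 ratio -0.43, percentile 0), 1 of 3 families of pentatricopeptide repeat proteins (57 genes, median -0.35, percentile 0, against -0.04 and percentile 39.62 for 13 genes and -0.10 and 20.57 for 12 genes in the other families), O-glycosyl hydrolases (17 genes, median -0.49, percentile 0.02) and tetratricopeptide repeat proteins (130 genes, median -0.13, percentile 0.03). Chaperonins of the TCP-1/cpn60 family lay just above (12 genes, median -0.38, percentile 0.25). All 291 tested nuclear genes with a product named ribosomal protein and no organelle in the name had a median of -0.58, with 270 below 0, 10 called lower and 0 higher. The 4 high families included RING/U-box proteins (148 genes, median 0.17, 5 called higher, percentile 100) and genes annotated as uncharacterized proteins (746 genes, median 0.08, percentile 99.99). The others were adenine nucleotide alpha hydrolases-like proteins (19 genes, median 0.32, percentile 99.96) and the glycosyl hydrolase superfamily (12 genes, median 0.48). The 13 genes pooled as glycosyl hydrolase family protein without their family numbers had a median of -0.06 (percentile 29.34). The protein kinase superfamily (199 genes, median 0.12, percentile 99.87) and WRKY transcription factors, regulators of defence (23 genes, median 0.34, percentile 99.84), came next. Other protein kinase families varied. They ran from percentile 27.62 for leucine-rich repeat protein kinases (65 genes, median -0.03) to 99.66 for CBL-interacting protein kinases (12 genes, median 0.30).

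The tests of explanations in the next paragraphs on dividing tissue, time of harvest and handling were chosen after the results they use had been seen. Those on transcript length and on shared PIP reads were chosen before.

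The cytosolic ribosomal protein genes were lower in the mutant library. A bias by transcript length and GC content is argued against, because the 13 genes lay at percentile 0 among random lists matched on expression, length and GC content, with a median of -0.69 against -0.40 to 0.14 for the middle 95% of those lists. A larger share of dividing tissue in the wild-type pool stays open and could not be decided. The dividing cell markers stood apart in the same direction (percentile 0.27, median -0.54), and the histone family did too, but this was known beforehand. None of the 9 tested markers was called, and the list held 288 reads in the wild type and 199 in the mutant. Their median differed from the ribosomal median by 0.15 (bootstrap interval -0.44 to 0.42). That interval is too wide to tell whether the markers fell more or less than the ribosomal genes. An effect of the genotype on growth stays open as well, as 1 pool per genotype holds no measure of differences between pools.

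The sugar-repressed genes were higher in the mutant library. The medians of the clock lists gave no sign of a harvest time that moves the morning and evening lists apart. Their evening minus morning median was -0.0393 (bootstrap interval -0.30 to 0.28). The morning genes themselves stood apart as higher by the median (0.27, percentile 99.3) but not by the mean (97.09). The evening genes ran from -0.49 to 0.94, and members of 1 list moving in opposite directions would not show in a median. A difference in harvest time that acts in this way, or that raises both sets, was not excluded. Harvest time could thus not be decided. Handling of the leaves before harvest stays open and could not be decided. The rapid wound and touch genes stood at percentile 100 with a median of 0.70, but this was known when the explanation was chosen. Their median differed from that of the sugar-repressed genes by -0.17 (interval -0.56 to 0.13). A shift of 1 list does not show what raised the other. A response to lower carbon supply in the mutant stays open and was not tested with 1 library per genotype.

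Reads at PIP1;2 in the mutant library were 12.9% of the wild-type level. Shared reads from the 12 other PIP genes are argued against at the 3' end, where 0% of the 265 windows of 36 bases in the last 300 bases of the annotated transcripts matched another PIP transcript with up to 2 mismatches. Over the whole transcripts 10.7% of windows matched, so reads from further upstream, if any were counted, remain open. Residual expression of the allele, or a plant in the pool of 10 with an intact gene, could give such reads too and was not tested.

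MAF5 lies in a cluster of related genes on chromosome 5. There AGL31 (AT5G65050) and MAF3 (AT5G65060) had 104 and 60 reads in the wild type and 128 and 63 in the mutant, and MAF4 (AT5G65070) had 24 and 11 (log2 ratio -1.18, -2.36 to -0.10), lower but not called. FLC (AT5G10140), the related flowering repressor, had 9 and 4 reads. These 4 genes were chosen after their values had been seen.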
